A study of Mus musculus with 38 samples.

How the data were processed

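Tail skin of mice was profiled by bulk RNA sequencing in 38 libraries. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was enriched with oligo(dT) beads, and libraries were built with a NEBNext Ultra kit and sequenced on a NovaSeq instrument. The submitters' processing notes name Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and DESeq2, without saying what each was used for. The genome build, the counting program and the use of strand were not given in the sources used here. Overlapping and antisense genes therefore could not be told apart, and no coordinates are given.

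The authors deposited 1 table of estimated counts per gene for all 38 libraries, with Ensembl identifiers and symbols. In 3108 of 19218 genes (16.2%) at least 1 value of these deposited expected counts was not whole, so values were rounded, which changed a library total by at most 22.1 counts. Of the 19220 rows of the table, 1 incomplete last row and 1 row with no symbol were left out. The identifiers of the 19218 genes used were all found in GENCODE M21, which was used only for gene length and GC content. Of 22028 protein-coding genes in that annotation, 19020 were in the table, and the others were not analysed here. The 3 annotation columns of the table were not used. Totals ran from 15.3 to 27.9 M counts per library.

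Groups were taken from the treatment named in the labels. The labels gave each library its own number, and nothing in them says whether separate libraries came from separate mice, so p-values measure the spread between these libraries. No pair of libraries in a group agreed within sampling noise (smallest chi-square per degree of freedom 7.58), and each counted as 1 replicate. Comparisons and tests, the gene lists and the rule for named genes were fixed before the data were examined. Differences between groups were tested with the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter and robust fitting, on the libraries of the groups compared. A gene was called when its Benjamini-Hochberg adjusted p lay under 0.05, with no fold limit. The interaction of induction and ABX was fitted on the 30 libraries of 4 groups. All adjusted p-values of genes come from edgeR unless another tool is named, all tests were two-sided, and standard errors (SE) of log2 fold changes were derived from the F statistic. CPM were computed on TMM-scaled totals, given as mean ± SD over the libraries of a group.

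The 34 gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists of a comparison, and again with an estimated correlation and with fry. Camera compares the members of a list with all other genes tested. The counts of members called are given over all genes tested and adjusted over the list alone. The level of a list in a library is the mean log2(CPM + 1) of its members. The genes named are the 10 largest rises and the 10 largest falls of each comparison among called genes with a mean of 1 CPM or more and a symbol that is not a provisional name, a pseudogene or an immune receptor segment. Where no gene was called, the 3 smallest p per direction are named. Up to 4 members per list with the smallest p were eligible as well, and 14 genes of pigment, T cell, interferon, stress kinase and antioxidant biology were reported in every comparison that measured them. 1 gene that the rule picked is not reported here. Genes named outside this rule are said to be chosen after their values were seen.

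Alternatives were RLE size factors, no low-count filter, a stricter filter (1 CPM in every library of a group), a fold of at least 2, DESeq2 1.42.0, limma-voom with quality weights, 1 surrogate variable (sva 3.50.0), all 38 libraries in one fit, the library number as a block, and leaving out each library. Chosen after the data were examined were a length and GC offset, the adipocyte level or the Hoxb13 level as a covariate, and leaving out libraries with Y-linked or gastrointestinal transcripts or vitiligo_ABX libraries 001 to 003. In simulations of 13780 to 14083 genes, edgeR recovered 62.7% of 1.5-fold, 92.5% of 2-fold and 98.5% of 4-fold changes for vitiligo against no induction. The first 2 were 32.8% and 76.1% for hippuric acid against vehicle, and 38.8% and 79.1% for vehicle against no induction. Of simulated calls 3.03% to 8.44% were false (nominal 5%). Real libraries hold structure beyond groups, so shares may differ.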

Results

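Tail skin of mice was sequenced in 6 groups. The series asked how skin changes in a mouse model of vitiligo, a disease in which skin loses its pigment cells, how ABX given to deplete gut microbes alters that skin, and what intraperitoneal hippuric acid, a glycine conjugate made from products of gut microbes, does to skin of wild type mice. There were 9 libraries with vitiligo induction (vitiligo), 9 without induction (no_induction), 6 with induction and ABX (vitiligo_ABX), 6 with ABX and no induction (no_induction_ABX), 5 with hippuric acid (hippuric_acid) and 3 with its vehicle (vehicle). The first principal component (21.6% of variance) set all 17 libraries given ABX or hippuric acid (4.98 to 37.8) apart from the other 21 (-43.9 to -4.00). Cohort, not labelled, cannot be told from either treatment. Ifng did not pass the count filter in any comparison and reached at most 0.274 CPM in a library, so a change in it was not detectable at this depth. Cd8a reached at most 2.02 CPM and passed the filter only in vitiligo_ABX against vitiligo and in the interaction, and Cxcl9 did not pass it in the 2 comparisons of pairs of groups that held no_induction_ABX.

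**Figure D1:**
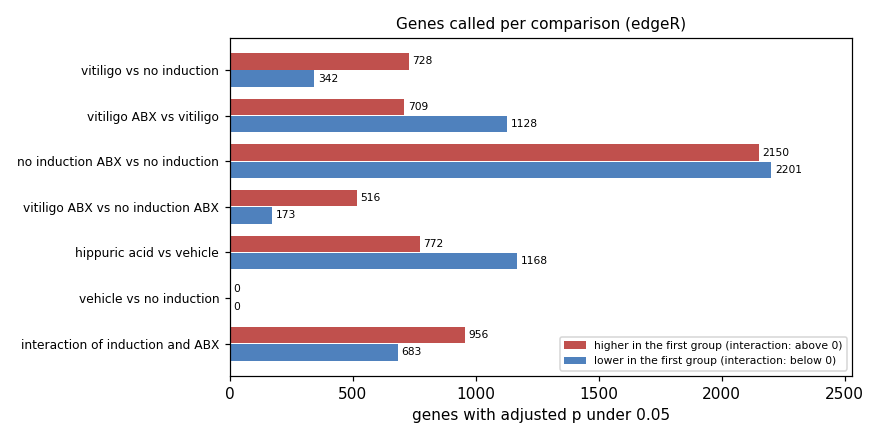
Number of genes called higher and lower in each comparison (x axis, genes; edgeR, adjusted p under 0.05). No_induction_ABX against no_induction had 4351 called genes, and vehicle against no_induction had 0.

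With vitiligo induction 4 of 21 pigment genes were lower in tail skin. In turn 20 of 21 adipocyte genes, 22 of 37 type I interferon genes and 20 of 42 genes of the interferon gamma response and antigen presentation were higher. Of these 4 lists only the adipocyte list was still called with an estimated correlation between its members. Pmel, which builds the fibrils of melanosomes, fell from 29.1 ± 6.39 to 11.6 ± 9.18 CPM (SD, n = 9 per group), a log2 fold change of -1.32 ± 0.36 (SE) with adjusted p = 0.0301. Dct and Tyrp1, enzymes of melanin synthesis, changed by -1.15 ± 0.33 (adjusted p = 0.0348) and -1.26 ± 0.35 (adjusted p = 0.0341). Each of Pmel, Dct and Tyrp1 lay under the no_induction mean in 9 of 9 vitiligo libraries. Lep, the gene of the fat hormone leptin, rose from 4.16 ± 3.25 to 80.3 ± 59.1 CPM (log2 fold change 4.29 ± 0.49, adjusted p = 3.96e-05), and 9 of 9 vitiligo libraries exceeded every no_induction library.

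Calls in the pigment genes depended on single libraries. Pmel was lost without any 1 of 6 libraries (adjusted p up to 0.0623, without vitiligo 047), Dct without any 1 of 9 (up to 0.0705, without vitiligo 000) and Tyrp1 without any 1 of 8 (up to 0.0695, without vitiligo 000). Oca2, which regulates the pH of melanosomes, was among the 10 largest falls (-1.45 ± 0.44, adjusted p = 0.0463) and was lost without any 1 of 13 libraries (up to 0.0906, without vitiligo 047). Tyr, the rate-limiting enzyme of melanin synthesis, stood at 7.54 ± 6.04 against 13.7 ± 4.78 CPM (-0.85 ± 0.37, adjusted p = 0.155) and Mlana at 4.18 ± 3.87 against 6.11 ± 3.59 (adjusted p = 0.478), and neither passed, though Tyr did without vitiligo 001 (-1.20, adjusted p = 0.0213). The other large falls were hair shaft genes with near-identical copies, whose single values are uncertain: Krtap4-13, Krtap4-2, Krtap9-1, Krtap4-6 and Krtap31-2 changed by -1.65 to -1.26. Tchhl1 of the hair follicle (-1.48), the complement gene C7 (-2.95, adjusted p = 0.0423) and P2rx1 (-1.68, adjusted p = 0.0412) fell too. The fall of C7 came mostly from no_induction 011 and 012 (109 and 119 CPM, against 0.363 to 20.02 in the other 7), and limma-voom gave -0.21 (adjusted p = 0.846). C7 was lost without any 1 of 8 libraries (adjusted p up to 0.0857, without no_induction 011), P2rx1 without any 1 of 12 (up to 0.0763, without vitiligo 000) and Krtap31-2 without any 1 of 12 (up to 0.0831, without no_induction 022). Besides Lep, the largest rises were Itgad (4.29), Nnat (4.18), Bpifa6 (3.25), the amino acid transporter Slc7a10 (2.74), haptoglobin Hp (2.72), Retnla (2.63), the muscle gene Myl1 (2.63) and the near-identical Mup9 (3.14) and Mup18 (2.76).

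**Figure D2:**
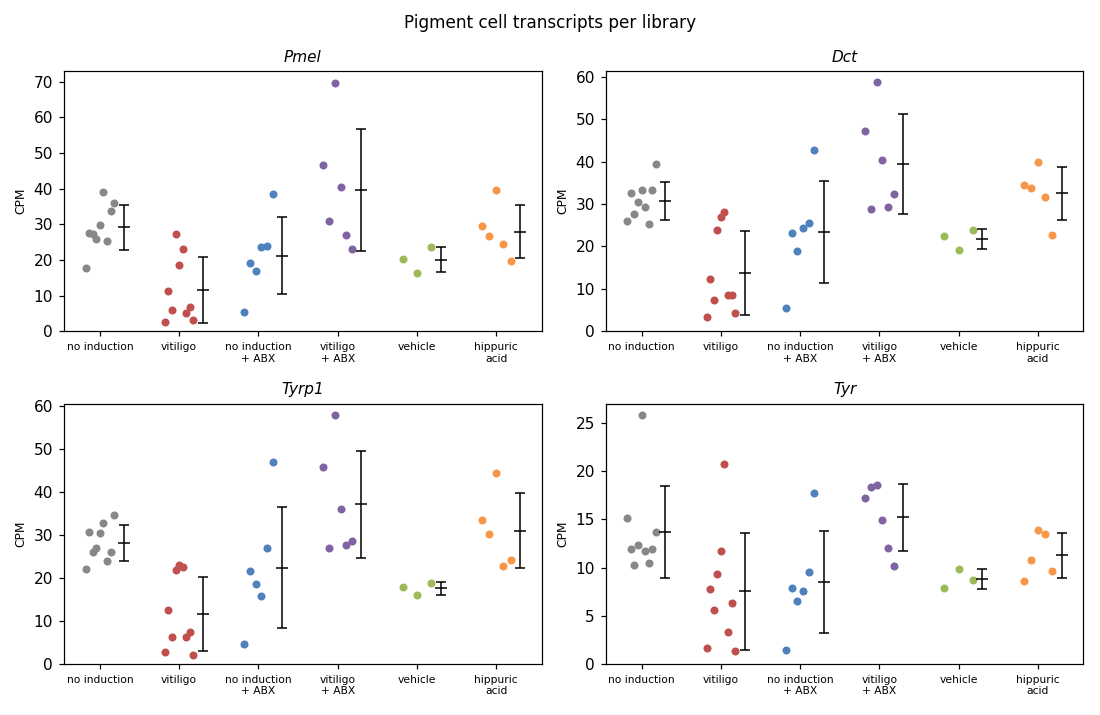
Levels of pigment genes (y axis, CPM) in each library (points) of the 6 groups, with black bars for the mean ± SD. Pmel averaged 11.6 CPM in vitiligo, 29.1 CPM in no_induction and 39.6 CPM in vitiligo_ABX.

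Of 21 measured adipocyte genes 20 rose and 0 fell, also adjusted over the list alone, with a median log2 fold change of 1.79. Plin4, which coats lipid droplets, rose by 1.97 ± 0.20 (adjusted p = 1.42e-05). The level of this list was 6.64 ± 0.42 in vitiligo and 4.99 ± 0.50 in no_induction on the log2 scale, with no overlap, and its call (camera adjusted p = 1.01e-47) held with an estimated correlation (adjusted p = 0.0175). Of 37 type I interferon genes 22 rose (33 adjusted over the list alone), among them Isg15 (1.3 ± 0.27, adjusted p = 0.00535) and Oas3 (1.98 ± 0.43, adjusted p = 0.00667). Of 42 genes of the interferon gamma response and antigen presentation 20 rose (35 adjusted over the list alone), among them H2-K1 (0.88 ± 0.14, adjusted p = 0.00061) and H2-Q7 (1.49 ± 0.25, adjusted p = 0.000768). Reads of H2 genes can be shared with related class I genes. Camera called both interferon lists (adjusted p = 2.33e-15 and 5.33e-17), and both calls were lost with an estimated correlation (adjusted p = 0.499 and 0.450). Of 31 T cell and cytotoxic lymphocyte genes 4 rose (15 adjusted over the list alone), which were Cd69, Itgae, Klrk1 and Il2rg, named after their values were seen (camera adjusted p = 9.24e-07, and adjusted p = 0.499 with an estimated correlation). Of 21 pigment genes 4 fell and 0 rose, over all genes and over the list alone (camera adjusted p = 0.00492, and adjusted p = 0.698 with an estimated correlation).

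Of 30 immediate early and heat shock genes 7 rose (13 adjusted over the list alone), with Klf2 (0.98 ± 0.20) and Nr4a1 (1.36 ± 0.30) in front (camera adjusted p = 0.0033, and adjusted p = 0.698 with an estimated correlation). Among 8 B cell genes Ighm rose (0.92 ± 0.27, adjusted p = 0.0438) and Prdm1, also a regulator of keratinocytes and sebaceous glands, fell (-0.35 ± 0.05, adjusted p = 0.000332), the same 1 and 1 adjusted over the list alone. The B cell list was not called (camera adjusted p = 0.791), and its test pointed down while its median (0.01) and mean (0.11) were positive. Ighm was lost without any 1 of 12 libraries (adjusted p up to 0.0931, without vitiligo 047). Camera also called hair follicle, basal keratinocyte and cell cycle genes lower and oxidative phosphorylation, mitochondrially encoded, macrophage and endothelial genes higher, all lost with an estimated correlation (adjusted p from 0.499 to 0.790). None of 39 NRF2 target genes was called over all genes or over the list alone (camera adjusted p = 0.427). Of 39 antioxidant enzymes 5 rose and 0 fell over all genes, and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.189). Cat, the catalase gene, rose by a log2 fold change of 0.60 ± 0.11 (adjusted p = 0.00115). It lay at 238 to 367 CPM in vitiligo and 168 to 272 CPM in no_induction, with 9 of 9 vitiligo libraries above the no_induction mean. Genes of reactive oxygen production (2 rose of 36, also adjusted over the list alone, camera adjusted p = 0.0554) were not called. Nor were those of the p38 stress kinases (3 rose and 1 fell of 37, and 5 and 3 adjusted over the list alone, camera adjusted p = 0.940), whose median was -0.01 while the mean was 0.17.

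Cxcl9, a chemokine that draws T cells, rose from 0.718 ± 0.588 to 4.14 ± 3.45 CPM (2.55 ± 0.47, adjusted p = 0.00166), above the no_induction mean in 8 of 9 libraries. Cxcl10 (1.5 ± 0.51, adjusted p = 0.073), Nos2 (0.37, adjusted p = 0.414), Mapk14 (-0.06, adjusted p = 0.57), Hmox1 (-0.02, adjusted p = 0.952), Nqo1 (-0.17, adjusted p = 0.294) and Sod2 (0.07, adjusted p = 0.502) did not pass. Cxcl10 passed without vitiligo 001 (1.61, adjusted p = 0.0361), no_induction 005 (1.70, adjusted p = 0.0446) or no_induction 022 (1.82, adjusted p = 0.0469). edgeR called 1070 of 13826 genes, 728 higher and 342 lower, of which 253 changed at least 2-fold. The count was 1744 by DESeq2, 5894 by limma-voom, 1683 with all 38 libraries, 686 with 1 surrogate variable, and 511 without the libraries that held gastrointestinal transcripts. It was 271 with the Hoxb13 level and 0 with the adipocyte level as a covariate (1195 at unadjusted p under 0.05), and a length and GC offset moved the share called higher from 68.0% to 53.3%. Leaving out 1 library gave 2571 (without vitiligo 001), 1634 (vitiligo 062), 1625 (no_induction 005), 711 (no_induction 021), 700 (no_induction 022) or 688 (no_induction 023). The lower count ranged from 161 (without vitiligo 047) to 993 (without vitiligo 001), with more genes higher than lower each time.

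Vitiligo_ABX was set against vitiligo, and cohort may differ too. With ABX, 20 of 21 adipocyte genes and 19 of 38 epidermal barrier genes were lower, and 7 of 21 pigment genes were higher and 1 lower. Pmel was 39.6 ± 17.1 CPM in vitiligo_ABX (n = 6) and 11.6 ± 9.18 in vitiligo (n = 9), a log2 fold change of 1.78 ± 0.44 with adjusted p = 0.0144. Dct rose by 1.53 ± 0.40 (adjusted p = 0.0177), with 6 of 6 ABX libraries above every vitiligo library. Lep fell from 80.3 ± 59.1 to 0.943 ± 1.12 CPM (-6.39 ± 0.68, adjusted p = 1.41e-05). The comparison shares its vitiligo libraries with the one before, so opposite signs in both are not independent.

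The largest rises were Hoxb13 (2.53 ± 0.46, adjusted p = 0.00181), a homeobox gene of the posterior body, and the pigment gene Oca2 (2.01). Others were the matrix or signalling genes Ltbp2 (2.07), Gdf10 (2.05), Mstn (2.03), Cemip (1.93), the cartilage proteoglycan Acan (1.92), Susd5 (1.89) and Osr1 (1.88), with P2rx1 (1.97). Hoxb13 was 23.1 ± 8.01 CPM in vitiligo_ABX and 4.03 ± 3.01 in vitiligo. Oca2 was lost without any 1 of 3 libraries (adjusted p up to 0.0835, without vitiligo_ABX 003) and Cemip without any 1 of 3. Cemip rested on vitiligo_ABX 001 (57.8 CPM, others 3.48 to 7.59), without which its change was 0.59 (adjusted p = 0.221). Falls were led by Itgad (-6.45), Lep, Pon1, Hp (-4.83), the fat hormones Adipoq (-4.37 ± 0.54, adjusted p = 6.18e-05) and Retn (-4.09), Nnat (-4.33), the lipid genes Thrsp (-3.95) and Cidec (-3.92), and Cyp2e1 (-4.25), an oxidase that can release reactive oxygen. Pon1 had 3 counts in all 6 vitiligo_ABX libraries against 476 in vitiligo, where it was 101.5-fold higher. The interval of 34.5 to 493.9 covers counting error only and not the spread between vitiligo libraries, which ran from 0.189 to 8.1 CPM.

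Of 21 adipocyte genes 20 fell and 0 rose, also adjusted over the list alone (camera adjusted p = 4.65e-60, and adjusted p = 0.0150 with an estimated correlation). Among them Agpat2 changed by -1.38 ± 0.13 and Lpl by -3.04 ± 0.29, and the list level of 3.8 ± 0.63 lay under every vitiligo library. Of 38 epidermal barrier genes 19 fell, and adjusted over the list alone 25 fell and 1 rose (camera adjusted p = 3.94e-14, and adjusted p = 0.476 with an estimated correlation). Krt2 went from 7882 ± 2007 to 3598 ± 991 CPM (-1.12 ± 0.20, adjusted p = 0.00152) and Krtdap by -1.10 ± 0.19. Of 75 nuclear genes of oxidative phosphorylation 35 fell (50 adjusted over the list alone), with Ndufa4 (-0.66 ± 0.13) and Atp5e (-0.77 ± 0.15) as examples. Of 53 ribosomal protein genes 42 fell (50 adjusted over the list alone), such as Rps12 (-0.78 ± 0.13) and Rpl17 (-0.67 ± 0.12). The ribosomal list was fixed as a check of library composition, which differed as well, with TMM factors of 1.014 to 1.096 with ABX against 0.928 to 1.005 without. Both lists were called (camera adjusted p = 1.03e-16 and 7.65e-25) and both calls were lost with an estimated correlation (adjusted p = 0.481 and 0.476). Of 39 antioxidant enzymes 14 fell and 1 rose (15 and 3 adjusted over the list alone), among them Gpx3 (-1.89 ± 0.30) and Sod1 (-0.64 ± 0.11). Cat fell by 0.56 ± 0.12 on the log2 scale (adjusted p = 0.00542), with 6 of 6 ABX libraries under the vitiligo mean. The antioxidant list was called (camera adjusted p = 0.000398, and adjusted p = 0.476 with an estimated correlation).

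Of 21 pigment genes 7 rose and 1 fell (9 and 1 adjusted over the list alone), including the receptor Ednrb (1.3 ± 0.20) and Mlph (0.52 ± 0.12), with camera adjusted p = 0.000219 and adjusted p = 0.476 with an estimated correlation. Genes of reactive oxygen production (5 fell and 1 rose of 36, and 6 and 1 adjusted over the list alone) were called lower (camera adjusted p = 0.0316, and adjusted p = 0.481 with an estimated correlation). NRF2 targets (8 fell and 3 rose of 39, and 9 and 3 adjusted over the list alone) were not called (camera adjusted p = 0.0747). Camera further called T cell, interferon gamma, mitochondrially encoded, epidermal activation, macrophage and B cell genes lower and basal keratinocyte, hair follicle, cell cycle, bone and cartilage, mast cell, endothelial and Schwann cell genes higher, all lost with an estimated correlation (adjusted p from 0.481 to 0.819). Tyr (1.02 ± 0.43, adjusted p = 0.126), Mlana (0.35, adjusted p = 0.679), Cd8a (-0.89, adjusted p = 0.248), and Cxcl9 (-1.10, adjusted p = 0.321) did not pass. Cxcl9 passed without vitiligo_ABX 003 (-2.89, adjusted p = 0.00435), which had 8.585 CPM against 0.398 to 1.03 in the other 5, and Tyr passed without vitiligo 001 (1.39, adjusted p = 0.0188). Neither did Cxcl10 (-0.04, adjusted p = 0.971), Nos2 (0.49, adjusted p = 0.323), Mapk14 (-0.11, adjusted p = 0.357), Hmox1 (-0.08, adjusted p = 0.807), Nqo1 (0.13, adjusted p = 0.411) and Sod2 (-0.03, adjusted p = 0.859). edgeR called 1837 of 14014 genes, 709 higher and 1128 lower, of which 461 changed at least 2-fold. The count was 4399 by limma-voom, 2811 with all 38 libraries, 2862 with 1 surrogate variable, 961 without the libraries that held gastrointestinal transcripts, 32 with the Hoxb13 level and 1 with the adipocyte level as a covariate. Leaving out vitiligo 001 gave 2803, vitiligo_ABX 004 gave 1183 and vitiligo_ABX 005 gave 1215. The excess of falls was not stable, with 1346 higher and 1457 lower without vitiligo 001 and 2239 higher and 2160 lower by limma-voom. The higher count was 467 (vitiligo library with the highest number left out) and 409, 419 and 471 (vitiligo_ABX 004, 005 and 006 left out in turn).

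In mice without induction, ABX went with lower levels of 39 of 42 hair, 19 of 21 adipocyte and 26 of 38 epidermal barrier genes and with higher levels of 34 of 37 type I interferon and 12 of 15 mast cell genes. None of these 5 lists was called with an estimated correlation. Krtap3-1 and Krtap3-3 of the hair shaft changed by -2.21 ± 0.20 (adjusted p = 2.24e-06) and -2.01 ± 0.17 (adjusted p = 1.12e-06) between 9 no_induction and 6 no_induction_ABX libraries, though such copies can share reads. Lep changed by -4.13 ± 0.66 (adjusted p = 0.00031), from 4.16 ± 3.25 to 0.228 ± 0.198 CPM, and 6 of 6 no_induction_ABX libraries lay under every no_induction library. Ifit1, an antiviral gene induced by interferon, rose from 2.50 ± 1.05 to 16.7 ± 17.8 CPM (2.74 ± 0.53, adjusted p = 0.00158).

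Other interferon genes made up most of the largest rises: Oas3 (2.23), Ifi44 (2.10) and the near-identical pairs Apol9a and Apol9b (2.79 and 2.18) and Ifit3 and Ifit3b (2.47 and 2.16). The transcription factor gene Sp9 (3.04 ± 0.56), the matrix gene Ccn3 (2.06) and the olfactory receptor gene Or8b53 (2.08, one of a large family) completed them. Falls were led by C7 (-6.63 ± 1.49, adjusted p = 0.00402), Cyp2e1 (-4.52), the adipocyte genes Retn (-4.11), Mrap (-3.98), Thrsp (-3.78) and Pck1 (-3.71), Mup18 (-3.64), Saa1 (-3.58) and Wfdc12 (-3.41), all with adjusted p under 0.05. The size of the C7 change rests in part on no_induction 011 and 012, which held Y-linked transcripts as above, and limma-voom gave -4.51. Hoxb13, named after its values were seen, rose from 8.28 ± 3.50 to 27.4 ± 2.28 CPM (1.74 ± 0.26, adjusted p = 0.000183), with no overlap between the groups.

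Of 42 hair follicle and hair shaft genes 39 fell and 0 rose, also adjusted over the list alone (median log2 fold change -1.40, camera adjusted p = 4.43e-23, and adjusted p = 0.277 with an estimated correlation). Of 37 type I interferon genes 34 rose (35 adjusted over the list alone), among them Parp14 (0.90 ± 0.16) and Ifit2 (1.54 ± 0.28), with camera adjusted p = 1.97e-12 and adjusted p = 0.561 with an estimated correlation. Libraries 002 and 004 of no_induction_ABX stood apart, with Ifit1 at 46.1 and 31.5 CPM against 4.25 to 8.24 in the other 4, and leaving out both at once was not tested. Of 21 adipocyte genes 19 fell, also adjusted over the list alone, among them Pnpla3 (-1.52 ± 0.18) and Lipe (-1.71 ± 0.21). The list level of 3.27 ± 0.39 lay under every no_induction library (camera adjusted p = 5.25e-18, and adjusted p = 0.277 with an estimated correlation). Of 38 barrier genes 26 fell (29 adjusted over the list alone), such as Tgm1 (-0.95 ± 0.11) and Lce1a1 (-1.26 ± 0.17, one of a family of copies), with camera adjusted p = 5.07e-13 and adjusted p = 0.397 with an estimated correlation. Of 15 mast cell genes 12 rose (13 adjusted over the list alone), among them Slc6a4 (0.97 ± 0.20) and Il1rl1 (1.49 ± 0.31), with camera adjusted p = 3.03e-07 and adjusted p = 0.561 with an estimated correlation. Of 19 clock genes 9 rose and 3 fell (9 and 4 adjusted over the list alone), with Per2 (0.92 ± 0.16) and Per3 (0.65 ± 0.11) among the rises, but the list was not called (camera adjusted p = 0.102).

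Of 39 antioxidant enzymes 12 fell and 2 rose, also adjusted over the list alone (camera adjusted p = 0.0386, and adjusted p = 0.561 with an estimated correlation), and Cat did not pass (0.08, adjusted p = 0.558). NRF2 targets (7 rose and 7 fell of 39, and 8 and 9 adjusted over the list alone) were not called (camera adjusted p = 0.882), with a median of 0.05 and a mean of -0.04. Camera also called interferon gamma, fibroblast, endothelial and Schwann cell genes higher and oxidative phosphorylation, epidermal activation and ribosomal protein genes lower, all lost with an estimated correlation (adjusted p from 0.397 to 0.632). Mlana fell (-1.59 ± 0.43, adjusted p = 0.0112), while Tyr (-0.68, adjusted p = 0.142), Dct (-0.39, adjusted p = 0.286) and Pmel (-0.45, adjusted p = 0.243) did not pass. Tyr passed without no_induction_ABX 006 (-1.04, adjusted p = 0.0241). Nos2, the inducible nitric oxide synthase, rose (0.86 ± 0.25, adjusted p = 0.0169), a call lost without no_induction_ABX 005 (adjusted p = 0.052). Cxcl10 (0.28, adjusted p = 0.648), Mapk14 (-0.14, adjusted p = 0.0967), Hmox1 (0.10, adjusted p = 0.745), Nqo1 (0.10, adjusted p = 0.557) and Sod2 (-0.04, adjusted p = 0.615) did not pass. edgeR called 4351 of 13971 genes, 2150 higher and 2201 lower, of which 675 changed at least 2-fold. The count was 6567 by limma-voom (3358 higher and 3209 lower) and 183 with the Hoxb13 level as a covariate.

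**Figure D3:**
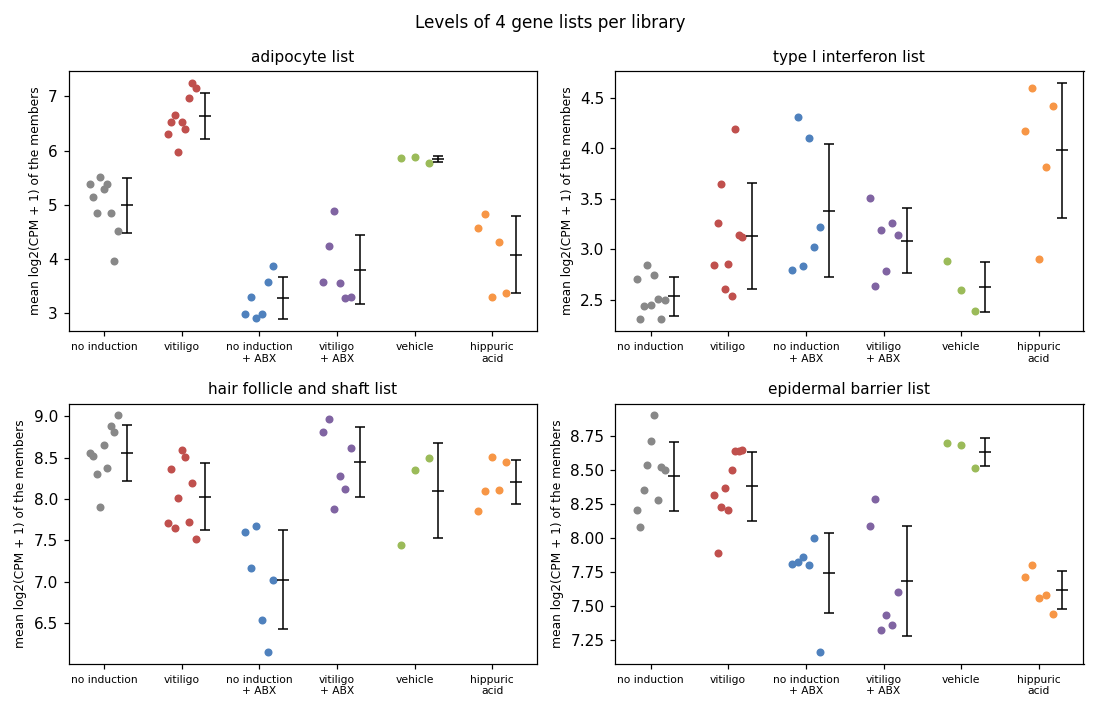
Level of gene lists (y axis, mean log2(CPM + 1) of the members) in each library (points) of the 6 groups, with black bars for the mean ± SD. The adipocyte level averaged 6.64 in vitiligo, 4.99 in no_induction, 5.84 in vehicle, 4.07 in hippuric_acid, 3.8 in vitiligo_ABX and 3.27 in no_induction_ABX.

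Among mice given ABX, induction went with higher levels of 21 of 42 hair genes and lower levels of 5 of 19 clock genes. Neither list was called with an estimated correlation (adjusted p = 0.332 and 0.352). The hair shaft keratin Krt40 rose from 12.5 ± 9.64 to 74.1 ± 20.8 CPM (n = 6 per group), a log2 fold change of 2.57 ± 0.54 with adjusted p = 0.0213. The hair follicle regulators Foxn1 and Dlx3 rose by 1.25 ± 0.23 (adjusted p = 0.0108) and 1.22 ± 0.24 (adjusted p = 0.0146). The level of the hair list lay above every no_induction_ABX library in 6 of 6 vitiligo_ABX libraries. None of the pigment genes reported throughout passed: Pmel was 39.6 ± 17.1 against 21.2 ± 10.8 CPM (0.91 ± 0.39, adjusted p = 0.2), with Tyr (adjusted p = 0.232), Dct (adjusted p = 0.24) and Mlana (1.40 ± 0.40, adjusted p = 0.0594) likewise. Mlana passed without no_induction_ABX 006 (1.75, adjusted p = 0.0169).

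The largest rises were keratin-associated genes of families with near-identical copies, Krtap5-3 (2.92), Krtap5-4 (2.67), Krtap29-1 (2.63), Krtap16-1 (2.61), Krtap5-2 (2.61) and Krtap10-4 (2.56), besides the calcium channel gene Cacna1i (2.76), the sebaceous desaturase gene Scd3 (2.69), Serpinb6e (2.59 ± 0.27, adjusted p = 0.0013) and Krt40. Krtap16-1 and Krt40 were lost without any 1 of 3 libraries (adjusted p up to 0.0643 and 0.0659, without no_induction_ABX 002). Falls were led by Idi2 (-2.12), Depp1 (-2.07), Paqr9 (-1.54), Or8b53 (-1.52), Dusp1 (-1.42 ± 0.16, adjusted p = 0.0013), a phosphatase that switches off p38 kinases, Esrrg (-1.41), Kcnj10 (-1.40), Cfap57 (-1.39), Snhg11 (-1.30) and Crocc2 (-1.30). Idi2 was lost without vitiligo_ABX 002 (adjusted p = 0.0506) and Paqr9 without no_induction_ABX 002 (adjusted p = 0.0511). Or8b53 and Kcnj10 were lost without any 1 of 7 libraries and Cfap57 without any 1 of 8, each with the highest adjusted p without no_induction_ABX 004 (0.0879, 0.0829 and 0.0873). Crocc2 was lost without any 1 of 6 (up to 0.0679, without no_induction_ABX 002).

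Of 42 hair genes 21 rose (36 adjusted over the list alone), with a median log2 fold change of 1.57 (camera adjusted p = 5.1e-29, and adjusted p = 0.332 with an estimated correlation). Of 19 clock genes 5 fell and 0 rose (9 and 1 adjusted over the list alone), among them Hlf (-0.43 ± 0.10, lost without any 1 of 3 libraries, adjusted p up to 0.0678 without no_induction_ABX 002). The clock list had camera adjusted p = 4.85e-05, and adjusted p = 0.352 with an estimated correlation. Of 15 mast cell genes 2 fell (4 adjusted over the list alone), which were Gata2 (-0.66) and Cma1 (-0.43), with camera adjusted p = 0.003 and adjusted p = 0.859 with an estimated correlation. Gata2 was lost without any 1 of 5 libraries (adjusted p up to 0.0656, without no_induction_ABX 005) and Cma1 without any 1 of 6 (up to 0.0839, without no_induction_ABX 005). Members of 3 further lists moved both ways, and none of these lists was called. Among NRF2 targets (3 rose and 3 fell of 39, and 3 and 4 adjusted over the list alone) Txnrd1 rose (0.81 ± 0.15) and Aldh3a1 fell (-0.63 ± 0.14), with camera adjusted p = 0.156. Among organic anion and glycine conjugation genes (1 rose and 2 fell of 14, also adjusted over the list alone) Acsm3, an acyl-CoA synthetase, rose (0.85 ± 0.17) and Cyp1a1, a target of the aryl hydrocarbon receptor, fell (-1 ± 0.18), with camera adjusted p = 0.201. Among sebaceous genes (2 rose and 3 fell of 24, and 4 and 6 adjusted over the list alone) Cidea fell (-0.57 ± 0.13), with camera adjusted p = 0.141. The call of Cidea was lost without any 1 of 5 libraries (adjusted p up to 0.0624, without no_induction_ABX 002).

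Camera also called pigment genes higher (1 rose of 21, and 5 adjusted over the list alone), with cell cycle, adipocyte and erythrocyte genes, and type I interferon genes lower, all lost with an estimated correlation (adjusted p from 0.672 to 0.859). None of 20 adipocyte genes was called by edgeR, over all genes or over the list alone. Cxcl10 (1.18, adjusted p = 0.12), Nos2 (-0.004, adjusted p = 0.997), Mapk14 (-0.03, adjusted p = 0.891), Hmox1 (-0.20, adjusted p = 0.764), Nqo1 (-0.14, adjusted p = 0.471), Sod2 (0.08, adjusted p = 0.648) and Cat (-0.05, adjusted p = 0.86) did not pass. edgeR called 689 of 13876 genes, 516 higher and 173 lower, of which 179 changed at least 2-fold. The count was 1283 by DESeq2, 1530 by limma-voom, 1223 with 1 surrogate variable, and 452 without vitiligo_ABX 001 to 003, with 225 of the 689 among them. These 3 libraries lay at 4.98 to 9.01 on the first principal component and at 13.8 to 19.1 CPM of Hoxb13, and 004 to 006 at 28.1 to 35.7 and at 27.5 to 33.9 CPM. The count was 438 with the adipocyte and 392 with the Hoxb13 level as a covariate, and 1253 with a length and GC offset, which moved the share called higher from 74.9% to 50.8%. Leaving out 1 library gave 359, 375 and 415 (vitiligo_ABX 001, 002 and 004) or 228, 290 and 353 (no_induction_ABX 002, 004 and 005).

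Whether ABX altered the effect of induction was tested as an interaction over the 30 libraries of these 4 groups, in which a positive value means that induction raised a gene more, or lowered it less, under ABX. Positive calls were made in 33 of 42 hair and 5 of 24 pigment genes. Negative calls were made in 19 of 37 type I interferon, 15 of 42 interferon gamma and antigen presentation and 6 of 21 adipocyte genes. None of these 5 lists was called with an estimated correlation. Pmel differed by 2.22 ± 0.57 log2 units (adjusted p = 0.0117) and Dct by 1.91 ± 0.52 (adjusted p = 0.016). B2m, the invariant chain of class I antigen presentation, differed by -1.20 ± 0.25 (adjusted p = 0.00276), and Cat by -0.66 ± 0.16 (adjusted p = 0.0069).

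Of 42 hair genes 33 had a positive call and 0 a negative one (38 and 0 adjusted over the list alone), among them Foxn1 (1.57 ± 0.24) and Dlx3 (1.60 ± 0.30). The hair list had camera adjusted p = 1.05e-32, and adjusted p = 0.0558 with an estimated correlation. The largest positive values were Krtap5-3 (4), Krtap5-4 (3.79), Krtap5-2 (3.70), Krtap5-1 (3.31) and Krtap29-1 (3.19), which share sequence with other copies, and Chrna4 (3.63), Lyg2 (3.50), Cacna1i (3.26), Chac1 (3.16) and Ctse (3.15). The most negative were Nnat (-4.21), the early response genes Fos (-3.17) and Dusp1 (-2.79), Depp1 (-2.96), Plppr4 (-2.76), Amy1 (-2.46) and the interferon genes Apol9a (-2.79), Oas3 (-2.71), Ifit1 (-2.61) and Ifit3 (-2.43). Apol9a was lost without any 1 of 2 libraries (adjusted p up to 0.0827, without no_induction_ABX 004), and Ifit1 and Ifit3 without no_induction_ABX 002 (adjusted p = 0.0737 and 0.0566).

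Of 37 type I interferon genes 19 had a negative call (33 adjusted over the list alone), among them Ifih1 (-1.24 ± 0.26) and Cmpk2 (-1.68 ± 0.42), with camera adjusted p = 1.69e-11 and adjusted p = 0.718 with an estimated correlation. These values rest in part on no_induction_ABX 002 and 004, which had the highest Ifit1 of their group (46.1 and 31.5 CPM). Of 42 interferon gamma genes 15 had a negative and 1 a positive call (25 and 1 adjusted over the list alone), among them B2m and H2-K1 (-0.97 ± 0.20), with camera adjusted p = 1.34e-09 and adjusted p = 0.718 with an estimated correlation. Of 21 adipocyte genes 6 had a negative call (8 adjusted over the list alone), with Lpl (-2.10 ± 0.36) and Plin4 (-1.72 ± 0.31), and camera adjusted p = 7.58e-07 became adjusted p = 0.718 with an estimated correlation. Of 24 pigment genes 5 had a positive call (9 adjusted over the list alone), with camera adjusted p = 7.56e-05 and adjusted p = 0.718 with an estimated correlation. Of 30 immediate early genes 7 had a negative and 1 a positive call, also adjusted over the list alone, with Klf2 at -1.75 ± 0.30 (camera adjusted p = 0.0147, and adjusted p = 0.812 with an estimated correlation). Of 17 basal keratinocyte genes 3 were positive and 1 negative, also adjusted over the list alone, with Cdh3 (1.02 ± 0.27) and Bcam (0.53 ± 0.12), but the list was not called (camera adjusted p = 0.131).

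NRF2 targets (3 positive and 5 negative of 39, and 4 and 8 adjusted over the list alone, camera adjusted p = 0.131) and antioxidant enzymes (2 and 3 of 39, and 5 and 3 adjusted over the list alone, camera adjusted p = 0.557) were not called. Camera also called T cell, mitochondrially encoded, macrophage and clock genes negative and cell cycle genes positive, all lost with an estimated correlation (adjusted p from 0.718 to 0.812). Tyr (1.69 ± 0.59, adjusted p = 0.0595), Mlana (1.93 ± 0.70, adjusted p = 0.0697), Cd8a (-1.32, adjusted p = 0.285) and Cxcl9 (-0.23, adjusted p = 0.908) did not pass. Tyr passed without vitiligo 001 (2.06, adjusted p = 0.00947), vitiligo 063 (1.80, adjusted p = 0.0479) or no_induction_ABX 006 (2.05, adjusted p = 0.0254). Mlana passed without vitiligo 001 (2.40, adjusted p = 0.00953) or no_induction_ABX 006 (2.27, adjusted p = 0.0413). Nor did Cxcl10 (-0.33, adjusted p = 0.813), Nos2 (-0.39, adjusted p = 0.581), Mapk14 (0.02, adjusted p = 0.912), Hmox1 (-0.20, adjusted p = 0.707), Nqo1 (0.02, adjusted p = 0.948) and Sod2 (-0.002, adjusted p = 0.994). edgeR called 1639 of 14310 genes, 956 positive and 683 negative, of which 561 differed at least 2-fold. The count was 4445 by limma-voom (2135 positive and 2310 negative) and 625 without vitiligo_ABX 001 to 003, with 540 of the 1639 among them. Leaving out vitiligo 001 gave 2679.

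Hippuric acid in wild type mice was tested against its vehicle, to ask what a raised level of this metabolite changes in skin. After hippuric acid 33 of 38 epidermal barrier and 15 of 21 adipocyte genes were lower, and 29 of 37 type I interferon and 9 of 15 mast cell genes were higher. Of these 4 lists only the barrier list was still called with an estimated correlation. Krt2, a keratin of the upper epidermis, fell from 10380 ± 876 CPM (n = 3) to 3240 ± 528 (n = 5), a log2 fold change of -1.68 ± 0.16 with adjusted p = 0.000493. Casp14, a protease of cornification, fell from 97.7 ± 5.82 to 39.8 ± 2.23 CPM (-1.30 ± 0.09, adjusted p = 0.000105). Ifit1 rose from 2.39 ± 0.844 to 37.7 ± 24.3 CPM (3.96 ± 0.75, adjusted p = 0.0116), a call lost without vehicle 001 (adjusted p = 0.0552). Lep fell from 23.7 ± 11.4 to 0.767 ± 0.676 CPM (-4.92 ± 0.65, adjusted p = 0.00235), with 5 of 5 libraries under every vehicle library.

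Among the largest rises, the muscle gene Acta1 (4.05 ± 0.58, adjusted p = 0.00185) stood beside interferon genes: Isg15 (3.21), Oasl2 (3.17), Ifi206 (3.17), Ifi44 (3.09) and the near-identical pairs Apol9a and Apol9b (3.21 and 3.15) and Ifit3b and Ifit3 (3.05 and 2.91). By limma-voom Ifit1 and the 8 interferon genes named here were not called (adjusted p from 0.226 for Ifit3 to 0.454 for Apol9a). Several of these calls were also lost on leaving out 1 library. Apol9a was lost without any 1 of 5 (adjusted p up to 0.108, without vehicle 001) and Oasl2 without any 1 of 3 (up to 0.0703, without vehicle 001). Ifi206 was lost without any 1 of 2 (up to 0.0636, without vehicle 002), as were Apol9b without any 1 of 2 (up to 0.0604, without vehicle 001) and Ifi44 without vehicle 003 (0.0555). Ifit3b was lost without any 1 of 3 (up to 0.0586, without vehicle 003) and Ifit3 also without any 1 of 3 (up to 0.0702, without vehicle 001). Falls were led by C7 (-6.86 ± 1.80, adjusted p = 0.0495), Lep, Cyp2e1 (-3.48), the ciliary gene Hydin (-3.23), Itgad (-3.16), Hp (-2.98) and the adipocyte genes Retn (-3.09), Mrap (-2.80), Cidec (-2.77) and Plin1 (-2.63). The size of the C7 change came from vehicle 001 (231.6 CPM, against 1.49 and 2.52 in the other 2 vehicle libraries), which also held Y-linked and gastrointestinal transcripts. Without it the change was -1.55 (adjusted p = 0.155), and C7 was lost without any 1 of 6 libraries. Cyp2e1 was lost without any 1 of 2 (adjusted p up to 0.112, without vehicle 001). Hoxb13, named after its values were seen, rose from 6.38 ± 2.61 to 31.4 ± 4.54 CPM (2.28 ± 0.24, adjusted p = 0.000617), with no overlap between the groups.

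**Figure D4:**
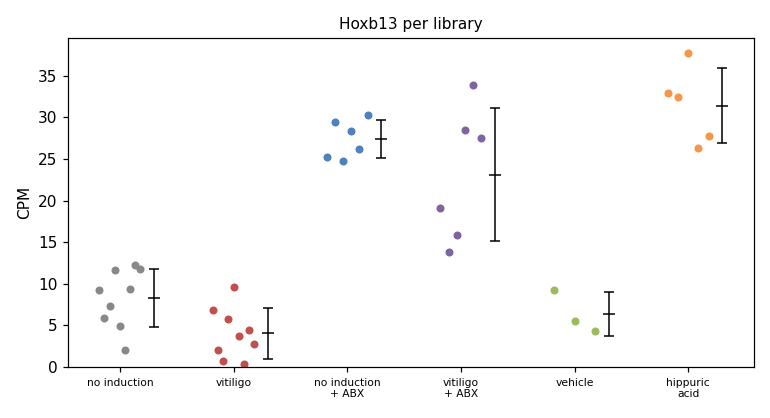
Hoxb13 (y axis, CPM) in each library (points) of the 6 groups, with black bars for the mean ± SD. The 17 libraries given ABX or hippuric acid lay at 13.8 CPM or above, and the other 21 at 12.3 CPM or below.

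Of 38 barrier genes 33 fell and 0 rose (35 and 0 adjusted over the list alone), with a median log2 fold change of -1.06, and the call (camera adjusted p = 2.15e-43) held with an estimated correlation (adjusted p = 0.0123). Of 37 type I interferon genes 29 rose (36 adjusted over the list alone), among them Eif2ak2 (0.94 ± 0.16) and Parp14 (1.37 ± 0.27), with camera adjusted p = 2.01e-19 and adjusted p = 0.401 with an estimated correlation. Library hippuric_acid 3 stood apart, with a list level of 2.91 against 3.81 to 4.60 in the other 4 and 2.39 to 2.88 with vehicle, and Ifit1 at 7.145 CPM against 21.9 to 64.4. limma-voom did not call Parp14 (adjusted p = 0.0952). Of 21 adipocyte genes 15 fell (18 adjusted over the list alone), such as Trarg1 (-2.35 ± 0.37). The list level was 4.07 ± 0.71 against 5.84 ± 0.06 in vehicle, with no overlap (camera adjusted p = 4.38e-16, and adjusted p = 0.401 with an estimated correlation). Of 15 mast cell genes 9 rose (14 adjusted over the list alone), such as Il1rl1 (1.27 ± 0.18) and Fcer1a (0.96 ± 0.18), with camera adjusted p = 2.78e-09 and adjusted p = 0.401 with an estimated correlation. Of 75 oxidative phosphorylation genes 43 fell (55 adjusted over the list alone), such as Atp5k (-1.51 ± 0.16) and Cox5a (-0.71 ± 0.09). Of 53 ribosomal protein genes 30 fell (50 adjusted over the list alone), such as Rps29 (-1.69 ± 0.22) and Rpl10 (-0.92 ± 0.12). The ribosomal list was fixed as a check of library composition, which differed as well, with TMM factors of 1.033 to 1.087 with hippuric acid against 0.921 to 0.982 with vehicle. The 10 most abundant genes held 6.23% to 7.54% against 8.84% to 9.79% of counts. Both lists were called (camera adjusted p = 2.44e-23 and 2.42e-22) and both calls were lost with an estimated correlation (adjusted p = 0.401 and 0.421).

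Of 39 NRF2 targets 6 fell and 3 rose (10 and 4 adjusted over the list alone), with camera adjusted p = 0.0442 and adjusted p = 0.452 with an estimated correlation. Of 39 antioxidant enzymes 10 fell and 2 rose (12 and 2 adjusted over the list alone), with camera adjusted p = 0.000164 and adjusted p = 0.423 with an estimated correlation. Genes of reactive oxygen production (2 rose and 6 fell of 36, also adjusted over the list alone) were not called (camera adjusted p = 0.324), nor was the p38 stress kinase list (3 fell of 37, also adjusted over the list alone, camera adjusted p = 0.371). Cat changed by -0.49 ± 0.14 (adjusted p = 0.0428), from 213 to 258 CPM with vehicle to 141 to 212 CPM with hippuric acid. Dct rose (0.57 ± 0.17, adjusted p = 0.0436) and Cxcl10 rose (1.86 ± 0.51, adjusted p = 0.0343). Each of the 3 was lost without any 1 of 6 libraries, with adjusted p up to 0.0985 (without hippuric_acid 3), 0.122 (without vehicle 002) and 0.0717 (without vehicle 002). Tyr (0.36, adjusted p = 0.226), Pmel (0.47, adjusted p = 0.154), Mlana (0.14, adjusted p = 0.655) and Cxcl9 (-1.14, adjusted p = 0.304) did not pass. The same held for Nos2 (0.83, adjusted p = 0.153), Mapk14 (-0.24, adjusted p = 0.0857), Hmox1 (-0.31, adjusted p = 0.196), Nqo1 (0.24, adjusted p = 0.471) and Sod2 (-0.14, adjusted p = 0.289). Mapk14 passed without vehicle 002 (-0.30, adjusted p = 0.0377) and Nqo1 without vehicle 001 (0.62, adjusted p = 0.0149).

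After hippuric acid, camera also called pigment, T cell, interferon gamma, bone and cartilage, fibroblast, macrophage, endothelial and Schwann cell genes higher and epidermal activation, sebaceous and clock genes lower, all lost with an estimated correlation (adjusted p from 0.401 to 0.637). edgeR called 1940 of 14097 genes, 772 higher and 1168 lower, of which 431 changed at least 2-fold. The count was 479 with the Hoxb13 level and 3 with the adipocyte level as a covariate, and a length and GC offset moved the share called higher from 39.8% to 29.3%. Leaving out 1 library gave 1217, 1149 and 1214 (hippuric_acid 1, 3 and 4). The split by direction was unstable, with 1445 higher and 1341 lower without vehicle 001, 427 and 983 without vehicle 003, and 399 to 469 higher without any 1 of hippuric_acid 1 to 4.

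Vehicle and no_induction are both wild type skin without hippuric acid, and setting them side by side shows how far the injected mice stood from the others. No gene was called by edgeR among 14175, with 509 at unadjusted p under 0.05, while DESeq2 called 7 and limma-voom 3. The smallest p for higher genes were those of Nnat (1.90 ± 0.32, adjusted p = 0.25), the clock gene Per1 (1.02 ± 0.17, adjusted p = 0.25) and Cish (0.77, adjusted p = 0.565). For lower genes they were those of Tyrp1 (-0.68 ± 0.14, adjusted p = 0.565), Ccl28 (-1.19, adjusted p = 0.999) and Sstr2 (-1.84, adjusted p = 0.999), and none passed. Tyr, Dct, Pmel, Mlana, Cxcl9, Cxcl10, Nos2, Mapk14, Hmox1, Nqo1, Sod2 and Cat all had adjusted p = 0.999, with log2 fold changes from -0.71 (Cxcl10) to 0.23 (Cat). The adipocyte level of the 3 vehicle libraries (5.78 to 5.88) lay above all 9 no_induction libraries (3.96 to 5.51). Of its 21 members 14 were higher adjusted over the list alone and 0 over all genes (camera adjusted p = 3.7e-32, and adjusted p = 0.119 with an estimated correlation). Camera also called barrier, clock and type I interferon genes higher and pigment, hair, cell cycle and erythrocyte genes lower, with 0 members called over all genes, and all were lost with an estimated correlation (adjusted p from 0.573 to 0.877). The count of 0 became 2 without vehicle 001, with Per1 among them (1.29, adjusted p = 0.00167), and 5 without the 3 libraries that held Y-linked transcripts, which were no_induction 011, no_induction 012 and vehicle 001.

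Genes called with induction were then followed into libraries that share none with that comparison. Of the 700 genes called higher and measured under ABX, 52.6% were higher in vitiligo_ABX than in no_induction_ABX, and 10 were called in the same direction and 4 in the opposite one, where independent lists would share 26.3 and 8.75. By camera with its preset correlation between genes the 700 genes pointed lower (p = 0.922) although the median (0.02) and mean (0.06) were above 0. Of the 200 with the smallest p, 187 were measured and pointed higher (p = 0.0153 with the preset and p = 0.525 with an estimated correlation). Of the 341 genes called lower, 25.8% were also lower under ABX, 2 were called lower and 18 higher (4.26 and 12.8 from independent lists). This set was higher by camera (p = 1.3e-06, and p = 0.365 with an estimated correlation). Fold changes of induction without and with ABX correlated at -0.15 (Spearman -0.20) across 13687 genes, which are not independent replicates.

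In hippuric_acid against vehicle, 44.7% of 720 genes called higher with induction were higher, and 50 were called higher and 113 lower (39.5 and 61 from independent lists). The set was lower by camera (p = 0.00873, and p = 0.623 with an estimated correlation). Of the 200 with the smallest p, 197 were measured, 15.2% of them were higher, and 2 were called higher and 74 lower (10.8 and 16.7 from independent lists). Those 197 were lower by camera (p = 7.67e-23, and p = 0.107 with an estimated correlation). Of 342 genes called lower, 56.7% were lower, and 35 were called lower and 5 higher (28.9 and 18.8 from independent lists). Camera gave p = 0.0422 (p = 0.724 with an estimated correlation, and p = 0.0755 for the 200 genes with the smallest p). Across 13785 genes the correlation of fold changes was -0.06 (Spearman 0.04).

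Genes called with ABX in mice without induction kept their direction with ABX in induced mice in 72.8% of 2132 higher and 63% of 2199 lower genes. Of these, 228 and 490 were called in the same direction and 19 and 55 in the opposite one, where independent lists would share 109 and 173, and 168 and 112. Camera called both sets in the same direction (p = 1.08e-08 and 7.92e-10), with p = 0.252 and 0.176 with an estimated correlation. The same ABX genes were also followed into hippuric_acid against vehicle, a test chosen after the data were examined. There 88.9% of 2139 higher and 76.8% of 2194 lower genes kept their direction, 458 and 648 were called in the same direction and 12 and 9 in the opposite one (118 and 184, and 179 and 121 from independent lists). Both sets were called by camera (p = 3.63e-27 and 6.87e-28) and with an estimated correlation (p = 0.0205 and 0.000768). Fold changes of the 2 comparisons, which share no library, correlated at 0.54 (Spearman 0.51) across 13897 genes.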

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

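Which libraries lay apart, and which genes differed in the effect of induction, was read with rules fixed before the data were examined, and no test in this part was chosen after a result was seen. Among 420 pairs of a named gene and a group, 24 (5.71%) held a library apart from its group by Dixon's ratio, spread over 15 libraries, and chance alone marks about 1 in 20 groups. In vitiligo_ABX, library 003 had high Cxcl9 (8.59 CPM, others 0.398 to 1.03), Cxcl10 (5.45 CPM), Thrsp (7.37 CPM) and Nqo1 (16.0 CPM). Library 001 of that group had high Cemip (57.8 CPM, others 3.48 to 7.59) and low Gata2 (16.1 CPM), library 002 low Paqr9 (0.114 CPM), and library 006 high Dusp1 (44.6 CPM) and Fos (33 CPM). In no_induction_ABX, library 004 had high Cxcl9 (0.939 CPM) and Scd3 (60.8 CPM), library 005 high Cma1 (296.1 CPM), and library 006 high Cyp2e1 (8.70 CPM) and low Sp9 (0.415 CPM, others 2.32 to 2.56). In no_induction, high values were those of Tyr in 011 (25.8 CPM), Klf2 in 012 (28.4 CPM), Cxcl9 in 022 (2.24 CPM), Bpifa6 in 003 (1.35 CPM), and Mapk14 (133.9 CPM) and Mup9 (1.01 CPM) in 005. In vitiligo they were Cmpk2 in 000 (16.6 CPM) and P2rx1 (15.5 CPM) and Prdm1 (65.9 CPM) in 063, and in hippuric_acid Nos2 in library 1 (3.72 CPM, others 1.42 to 1.84). All libraries stayed in every comparison, and calls of named genes lost or gained without 1 of them are given with the genes.

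The effect of induction differed with and without ABX for 54 of the named genes. Hair genes had positive log2 differences: Krtap5-3 3.996, Krtap5-4 3.79, Krtap5-2 3.70, Krtap5-1 3.31, Krtap29-1 3.19, Krtap10-4 3.11, Krtap16-1 3.11, Tchhl1 3.04, Krtap4-2 2.93, Krt40 2.87, Krtap31-2 2.80, Krtap9-1 2.79, Krtap4-13 2.65, Krtap4-6 2.61, Dlx3 1.60 and Foxn1 1.57. Pigment genes did too, with Oca2 2.47, Pmel 2.22, Tyrp1 1.99 and Dct 1.91, as did Chrna4 3.63, Lyg2 3.50, Cacna1i 3.26, Chac1 3.16, Ctse 3.15, Cdh3 1.02, Txnrd1 0.99, Prdm1 0.74 and Bcam 0.53. Interferon and antigen presentation genes had negative differences: Apol9a -2.79, Oas3 -2.71, Ifit1 -2.61, Ifit3 -2.43, Cmpk2 -1.68, H2-Q7 -1.47, Ifih1 -1.24, B2m -1.20 and H2-K1 -0.97. So had the early response genes Fos -3.17, Dusp1 -2.79, Nr4a1 -2.10 and Klf2 -1.75 and the adipocyte genes Lpl -2.10 and Plin4 -1.72. The others were Nnat -4.21, Depp1 -2.96, Plppr4 -2.76, Amy1 -2.46, Or8b53 -1.85, Snhg11 -1.45, Cfap57 -1.45, Paqr9 -1.24, Aldh3a1 -0.70 and Cat -0.66. Apol9a was lost without any 1 of 2 libraries (adjusted p up to 0.0827, without no_induction_ABX 004), and Ifit1 and Ifit3 without no_induction_ABX 002 (adjusted p = 0.0737 and 0.0566).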

How the results depend on the processing

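The fits with adipocyte or Hoxb13 level, with a length and GC offset, and without the libraries that held gastrointestinal or Y-linked transcripts or without vitiligo_ABX 001 to 003 were chosen after results were seen, and the other settings before the data were examined. The count of called genes moved between settings. Of 200 calls in named genes, DESeq2 kept 198, RLE size factors 199, limma-voom 182 and the fit of all 38 libraries 158 of 166, while 39 were lost on leaving out at least 1 library. No call changed direction in these, the only fits checked. Most called lists were lost with an estimated correlation, fewer by fry, and a lost call says more about a list's members than about mice. The adipocyte and Hoxb13 levels differ between the groups compared, so a fit that adjusts for them also removes what the groups share with them. The cause of these movements was not tested.

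The replicate numbers do not show which libraries belong together. Libraries of the same number correlated at -0.18 to 0.291 after group means were removed, and in no comparison with at least 3 shared numbers did every such pair exceed 0.1. Taking the numbers as blocks left 2 pairs in vitiligo_ABX against vitiligo (64 genes called), 4 in no_induction_ABX against no_induction (1436), 6 in vitiligo_ABX against no_induction_ABX (793), 3 in hippuric_acid against vehicle (879) and 3 in vehicle against no_induction (2), with fewer libraries than the unblocked fits except in vitiligo_ABX against no_induction_ABX, where the 6 pairs hold all 12 libraries.

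For vitiligo against no_induction (1070 called) the count was 253 at a fold of at least 2, 1744 by DESeq2, 5894 by limma-voom, 1683 with all 38 libraries, 686 with 1 surrogate variable, 511 without the libraries with gastrointestinal transcripts, 1370 without those with Y-linked transcripts, 0 with the adipocyte level (1195 at unadjusted p under 0.05) and 271 with the Hoxb13 level. It was 688 to 2571 leaving out 1 library. For vitiligo_ABX against vitiligo (1837) it was 461 at a fold of at least 2, 4399 by limma-voom, 2811 with all 38 libraries, 2862 with 1 surrogate variable, 961 without the libraries with gastrointestinal transcripts, 1 with the adipocyte level and 32 with the Hoxb13 level, 2803 without vitiligo 001, and 1183 and 1215 without vitiligo_ABX 004 and 005. For no_induction_ABX against no_induction (4351) it was 675 at a fold of at least 2, 6567 by limma-voom and 183 with the Hoxb13 level.

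For vitiligo_ABX against no_induction_ABX (689 called) the count was 179 at a fold of at least 2, 1283 by DESeq2, 1530 by limma-voom, 1223 with 1 surrogate variable, 1253 with a length and GC offset, 438 with the adipocyte level, 392 with the Hoxb13 level and 452 without vitiligo_ABX 001 to 003. It was 359, 375 and 415 without vitiligo_ABX 001, 002 and 004, and 228, 290 and 353 without no_induction_ABX 002, 004 and 005, and at most 863 (without 006). For hippuric_acid against vehicle (1940) it was 431 at a fold of at least 2, 3 with the adipocyte level, 479 with the Hoxb13 level, and 1217, 1149 and 1214 without hippuric_acid 1, 3 and 4, and at most 2786 (without vehicle 001). For vehicle against no_induction edgeR called 0 (509 at unadjusted p under 0.05), DESeq2 7 and limma-voom 3, and edgeR called 5 without the libraries with Y-linked transcripts, 5 without those with gastrointestinal transcripts and 2 without vehicle 001. For the interaction (1639) it was 561 at a fold of at least 2, 4445 by limma-voom, 625 without vitiligo_ABX 001 to 003 and 2679 without vitiligo 001, and at least 1177 on leaving out 1 library (vitiligo_ABX 002).

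With an estimated correlation called lists went from 13 to 1 in vitiligo against no_induction, 20 to 1 in vitiligo_ABX against vitiligo and 13 to 0 in no_induction_ABX against no_induction. They went from 8 to 0 in vitiligo_ABX against no_induction_ABX, 19 to 1 in hippuric_acid against vehicle, 8 to 0 in vehicle against no_induction and 11 to 0 in the interaction. In that order fry called 4, 12, 18, 3, 9, 0 and 4. It kept 4, 11, 12, 2, 9, 0 and 4 of the first calls. Some lists changed direction, and none of them was called in the setting named. By fry these were, in vitiligo against no_induction, p38 stress kinases (adjusted p = 0.844), clock (0.996) and organic anion transport (0.844), in vitiligo_ABX against no_induction_ABX T cells (0.833) and macrophages (0.913), in vehicle against no_induction ribosomal proteins (0.985) and in the interaction the epidermal barrier (0.974). With RLE size factors they were organic anion transport in vitiligo against no_induction (0.982) and neutrophils in vitiligo_ABX against vitiligo (0.984).

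Without the low-count filter the lists that changed direction were list organic anion transport and glycine conjugation, vitiligo vs no_induction (adjusted p = 0.552), list B cell and plasma cell, vitiligo vs no_induction (0.943), reactive oxygen production (0.984) and skeletal muscle (0.935) in no_induction_ABX against no_induction, T cells (0.343), macrophages (0.887) and skeletal muscle (0.756) in vitiligo_ABX against no_induction_ABX, and ribosomal proteins (0.934) in vehicle against no_induction. Without genes that another list holds they were organic anion transport (0.483) and epidermal activation (0.928) in vitiligo against no_induction, p38 stress kinases (0.746) in vitiligo_ABX against vitiligo and NRF2 targets (0.870) in no_induction_ABX against no_induction.

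Genes called higher with induction did not differ from other genes under ABX by camera past the threshold when all were used (p = 0.922) and were higher, by its preset correlation, when the 200 with the smallest p were used (187 measured, p = 0.0153). With an estimated correlation these 187 had p = 0.525 and the genes called lower p = 0.365. After hippuric acid the genes called higher with induction had p = 0.623 and those called lower p = 0.724 with an estimated correlation, and p = 0.0755 for the 200 of the latter with the smallest p. The ABX genes in induced mice had p = 0.252 (higher) and 0.176 (lower) with an estimated correlation. Named genes whose direction changed were all uncalled. Under another tool or size factor, or without the library whose removal gave the highest adjusted p, they were Hmox1 in vitiligo against no_induction (0.0948 by limma-voom), Cxcl10 (0.0274) and Sod2 (0.0102) in vitiligo_ABX against vitiligo leaving out a library, Nos2 (0.283 by limma-voom) and Hmox1 (0.0314 leaving out a library) in vitiligo_ABX against no_induction_ABX, and Nos2 (-0.0167 leaving out a library) and Hmox1 (-0.0139 by limma-voom) in vehicle against no_induction. They also were Mapk14, interaction of induction and ABX (-0.0896 by limma-voom and -0.0092 leaving out a library), and in the same comparison Hmox1 (0.0368 leaving out a library), Nqo1 (-0.0233 by limma-voom and -0.0006 leaving out a library) and Sod2 (0.0035 with RLE size factors, 0.0037 by DESeq2, 0.0487 by limma-voom and 0.0004 leaving out a library). Without some other library the sign also changed for Hmox1 in vitiligo_ABX against vitiligo (up to 0.0372) and no_induction_ABX against no_induction (down to -0.1362), and for Cxcl9 in vehicle against no_induction (down to -0.1086) and the interaction (up to 0.2636). Over all these fits Cxcl10 in vitiligo_ABX against vitiligo reached 0.2707, Sod2 there 0.0234, Hmox1 in vehicle against no_induction -0.1333 and Nqo1 in the interaction -0.0403.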

Other observations

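The Hoxb13 fold test, the test of shared reads and the test of random removals were chosen after the results they concern were seen, as were the leave-one-out criterion of the slope test and the patterns weighed here. Fibroblast, Schwann cell and endothelial lists were each called higher in 2 comparisons that share no library. This was not particular to them, since the endothelial list was also called higher in vitiligo against no_induction and in vitiligo_ABX against vitiligo, and the Schwann cell list in the latter. In the 2 comparisons each call was lost with an estimated correlation (adjusted p = 0.603, 0.397 and 0.632 in the first and 0.401, 0.540 and 0.522 in the second). Whether the same members changed was not tested. Of 40 fibroblast and matrix genes 13 were higher and 1 lower both in no_induction_ABX against no_induction and in hippuric_acid against vehicle. Schwann cell genes were higher in 10 and 3 of 19, and endothelial genes in 8 and 5 of 25, with none lower. In 27 of 232 list tests the median, the mean and the test differed in sign, and 0 of these 27 were called.

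Other splits of the same libraries show how often a random grouping called as many genes, taking the libraries as exchangeable. Few did so for vitiligo against no_induction (2 of 100 splits called as many as 1070, the real one included, highest other 1928), vitiligo_ABX against vitiligo (2 of 100, 1837, highest other 2506), no_induction_ABX against no_induction (1 of 100, 4351, highest other 2225), vitiligo_ABX against no_induction_ABX (1 of 100, 689, highest other 5) and hippuric_acid against vehicle (1 of 56, 1940, highest other 0). For the interaction (1 of 100, 1639, highest other 1075) chance stays open, as splits also remove the effect of induction. For vehicle against no_induction, where edgeR called 0, the splits say nothing, since all 100 call at least 0. There 1 split called 731, and in the first 2 comparisons 1 other split called more than the real one, which points to a structure among the libraries beyond their groups.

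The fold changes of hippuric_acid against vehicle followed those of no_induction_ABX against no_induction (correlation 0.537 across 13897 genes), and only 1 of the 56 splits of the 8 hippuric acid and vehicle libraries, the real one, gave so high a value (highest other 0.476). With a length and GC offset in both comparisons the correlation was 0.505, which argues against such a bias as the whole cause. The 2 sets of mice might instead differ from their controls in cohort or in the place sampled along the tail, since Hoxb13, a gene of the posterior body, was 26.3 to 37.7 CPM with hippuric acid and 4.29 to 9.30 CPM with vehicle (log2 fold change 2.28), and these 2 explanations cannot be told apart here. In these 2 comparisons the place of sampling rests on this 1 called gene. Of 5 posterior patterning genes, a list also chosen afterwards, only Hoxb13 was called (median log2 fold change 0.197, p = 0.0158 with a preset and 0.0522 with an estimated correlation). In no_induction_ABX against no_induction Hoxb13 was higher and Hoxc13 lower, and 2 others were not called (p = 0.455 with the preset correlation). Slopes on Hoxb13 within vitiligo and no_induction correlated with hippuric acid fold changes at 0.076 (Spearman 0.043, 13784 genes), as high in 20 of 56 splits (highest other 0.5). This value does not favour the place sampled, left open by a later leave-one-out criterion (-0.138 to 0.227). A shared response of skin to ABX and to hippuric acid stays a hypothesis that these libraries do not separate from cohort.

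Adipocyte genes rose with induction and fell in vitiligo_ABX against vitiligo, no_induction_ABX against no_induction and hippuric_acid against vehicle, and a candidate explanation is the share of adipose tissue in the sampled skin. Across 21 members the fold changes correlated with slopes on the adipocyte level within groups at 0.637 (p = 9e-04), 0.783 (p = 2e-05), 0.839 (p = 1e-05, the smallest the permutations can give) and 0.692 (p = 0.00028) in that order, with adjusted p = 9e-04, 4e-05, 4e-05 and 0.000373, Spearman 0.803, 0.864, 0.806 and 0.839, and 0.485, 0.698, 0.804 and 0.591 without the 2 farthest members. Place along the tail may contribute, as Hoxb13 correlated with the adipocyte level within groups at -0.367 (p = 0.0197, 38 libraries, -0.326 without the 2 farthest, Spearman -0.384), though no single group passed (-0.4 in vitiligo, -0.495 in no_induction, -0.814 in vitiligo_ABX and 0.615 in no_induction_ABX, adjusted p = 0.286, 0.268, 0.139 and 0.268). Reads of a few other genes are unlikely to account for it, since 20 of 21 members were called in vitiligo against no_induction. A change of adipocytes themselves stays open beside a change in how much fat was sampled.

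Gastrointestinal transcripts stood out in 5 libraries, which were vitiligo 000 and 260, no_induction 011 and 012 and vehicle 001, and RNA of gastrointestinal tissue is a candidate source. All 28 detected genes (100%) of a second list of 30, of which none is in an adipose or skin list, were higher there than in the other 33 libraries, with Fcgbp (80.5 against 59.7 CPM), Slc5a1 (51.8 against 36.8) and Lgals4 (6.38 against 4.25) as the most abundant. Skin without such RNA thus expresses the most abundant of them too, and the clearest were scarce, such as Lypd8 (3.78 against 0.213 CPM). Without these libraries 511 genes were called in vitiligo against no_induction instead of 1070 (at least 688 leaving out 1). Removing as many at random gave as few genes in 20 of 60 draws (203 to 4498, median 642.5). Draws could include these libraries, so their part in the drop stays open.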
